A study of Homo sapiens with 2 samples.

How the data were processed

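ATAC-seq libraries from 2 cell populations were compared: MCF7-derived breast cancer stem cells overexpressing SETD4 from a lentiviral vector, and the same kind of cells overexpressing GFP, 1 library each. Per the labels' protocols, nuclei were transposed with Tn5 for 30 min at 37 °C and the products amplified by PCR and sequenced. The groups were taken from the sample titles. No replicates were pooled, and no sample was left out.

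The data are 1 table of merged sites deposited for the whole series, with 4982 rows for 4816 distinct sites; a site that overlaps several genes has a row for each, and each site was used once. Per the submitters' processing notes, Bowtie2 2.2.9, MACS2 and HOMER were used; their settings, the removal of duplicate reads and the Tn5 offset of read ends are not given in the sources used here. If PCR duplicates were kept, reads are not independent molecules. The notes list the mouse build mm9. The file itself holds human Ensembl gene identifiers and GRCh38 scaffold names, and of 961 closest genes with a symbol found on the same chromosome in RefSeq's GRCh38.p14 table, 88.7% start within 10 kb of the RefSeq start and 233 at the identical base, so the coordinates were read as GRCh38. Site starts are counted from 0 in the file (1 site starts at 0) and are printed here counted from 1.

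Per the file headers, the table gives raw read counts per site and library; these are whole numbers with no normalization. The deposited RPM values (reads scaled to the library total) equal the count plus 1, scaled by 1 constant per library, within 0.000381% in every site. That constant gives the library totals of 124 M reads (GFP) and 72.5 M (SETD4); which reads those totals include is not given in the sources used here. The deposited fold enrichment, a ratio, is RPM over the level expected if reads were spread evenly over a genome of 3099.75 Mb. The authors' log2 values are the log2 ratio of RPM in SETD4 to RPM in GFP, and this was checked in every site. Plus and minus signs in the deposited table, other than numbers, record whether each site overlaps a peak that the authors called in each library. The table's distance to the closest transcription start site and its gene overlaps were used as the authors give them.

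With 1 library per group there is no estimate of replicate error, so no count model and no test across sites or genes was run. Intervals for shares are exact binomial (Clopper-Pearson) 95% intervals, those for the ratio of 2 counts come from the exact binomial interval of one count given their sum, and those for medians are from 2000 bootstrap resamples of sites. The first 2 kinds cover counting error only, and the third the spread between sites. At the median count of 71 reads per site in the GFP library and 66 in the SETD4 library counting error alone is sizeable, and sites with the lowest counts are the least certain. Comparisons were the authors' calls and their ratios (all sites), the genome location of each class, the chromosomes, and 14 gene lists.

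A site was assigned to each named gene it overlaps and otherwise to the gene with the closest start, where the file gives a symbol; 2091 sites were assigned to 1711 genes and 2725 had no named gene. Symbols were matched to RefSeq, including older ones, for 1660 genes, of which 1643 are protein-coding. A gene's value is the mean log2 ratio of its sites. For each list, the median over measured genes was placed among 10000 random lists of the same size drawn from the same 10 bins of mean RPM. Gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named SETD4 and EEF1A1; the 10 largest and 10 smallest ratios among sites called in 1 library only, above the median of sites in mean RPM and assigned to a protein-coding gene, 1 site per gene (only 8 existed for GFP); and up to 3 members per list with a site called in 1 library only, or else the member with the largest absolute value. Other list members are named where few were measured. Alternatives were thresholds of 1.5-fold and 4-fold, centring on the median ratio, only sites above the median in RPM, no added count, merging of sites within 500 bp, autosomes only, other windows around start sites, and other ways to assign sites to genes.

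On simulated data made from the real sites' levels, with 4816 simulated genes and lists of 10, the list percentile fell outside the middle 95% for 4.00% of unshifted lists, 57.0% of lists shifted by 1 on the log2 scale and 100% of lists shifted by 2. The ratio interval held the true value in 95.9% of 2000 simulated sites. The lists measured here have at most 5 genes, so the percentiles have less power than that. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.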

Results

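ATAC-seq, which reads the DNA that the Tn5 transposase can reach and so maps open chromatin, was carried out on breast cancer stem cells derived from MCF7, an oestrogen-receptor-positive human breast cancer line. The comparison asks how the chromatin of stem cells that overexpress SETD4, a lysine methyltransferase, differs from that of stem cells that overexpress GFP. The labels describe the SETD4 cells as high, and the GFP cells as low, in H4K20me3, a histone mark of heterochromatin. Both were grown as tumorspheres for 2 weeks. Each group had 1 library, so no difference below has a replicate check, no p-value across sites or genes was computed, and every interval covers counting error or the spread between sites only. The GFP library had an implied total of 124 M reads and the SETD4 library 72.5 M. The deposited table held 4816 distinct sites. They took 1033747 reads of the GFP library, or 0.834% of its total (exact 95% interval 0.833% to 0.836%), and 1068997 reads of the SETD4 library, or 1.48% (1.47% to 1.48%). The median count per site was 71 in the GFP library and 66 in the SETD4 library. Most reads of both libraries thus lay outside the sites, and 0 of the 20 genes listed for constitutive promoters had a site. How far the sites mark open chromatin is therefore uncertain.

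The SETD4 gene itself stood furthest apart between the libraries. A total of 5 separate stretches of it, 280 to 377 bp wide, were called in the SETD4 library and not in the GFP library, and each was centred on an exon or on the 3′ untranslated region. Together they held 74971 reads in the SETD4 library (1035 RPM, reads scaled to the library total) and 92 in the GFP library (0.742 RPM), a ratio of 1394 (95% counting interval 1136 to 1729). Positions are given on human GRCh38. The site over exon 6 (chromosome 21, 36043682 to 36044058) had 21529 against 17 reads, and that over exon 2 (36057006 to 36057306) had 13393 against 14. The sites over exon 7 (36041707 to 36041986) and exon 9 (36038048 to 36038373) had 7795 against 16 and 12724 against 20 reads. The site in the 3′ untranslated region (36036017 to 36036353) had 19530 against 25 reads. These 5 sites made up 7.01% of all SETD4-library reads in the table. The labels describe a vector that carries the SETD4 open reading frame, so reads from the vector and from the genomic exons cannot be separated in these counts. EEF1A1, whose promoter (EF1a) drives SETD4 in the vector, had 0 sites in the table, which lists called sites only.

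**Figure D1:**
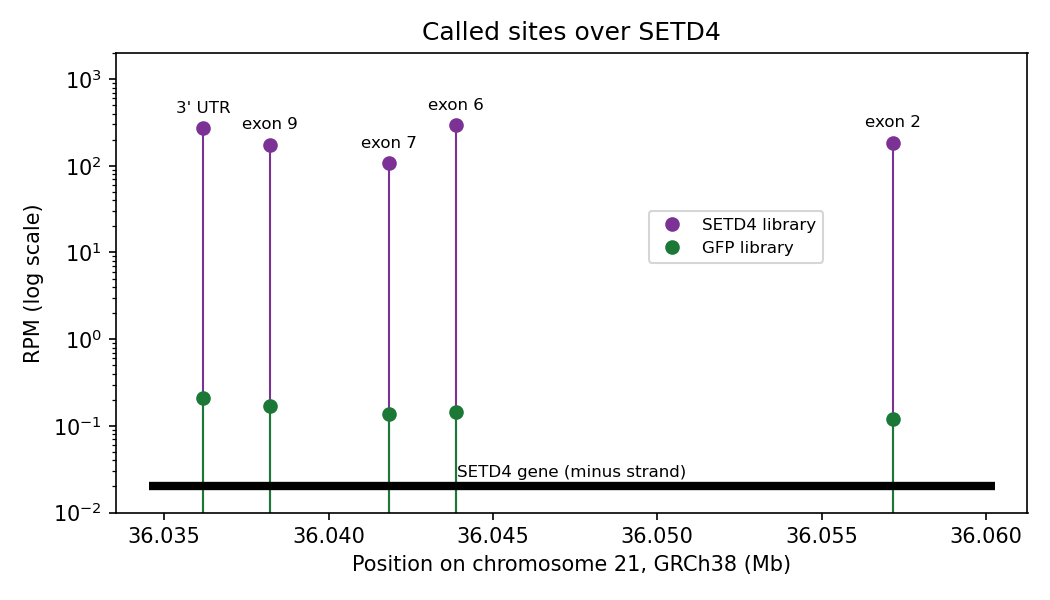
RPM (log scale) at the 5 called sites over SETD4 against their position on chromosome 21, with 1 point per library and site; the black bar is the gene. The SETD4 library lies between 107.6 and 297.1 RPM and the GFP library between 0.121 and 0.210.

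Most sites had a higher RPM in the SETD4 library. Of the 4816 sites, 3820 were higher in the SETD4 library and 996 in the GFP library. The median log2 ratio of SETD4 to GFP was 0.77 (interquartile range 0.13 to 1.14; bootstrap 95% interval over sites 0.75 to 0.79), a ratio of 1.71. That value equals the log2 ratio of the library totals, 0.77, so that the median site had the same raw count in both libraries. By the authors' calls, 2744 sites were found in both libraries, 1263 in the SETD4 library only and 809 in the GFP library only. Sites called in both had a median log2 ratio of 0.80, those called in SETD4 only 1.13 and those called in GFP only -0.35. A call in 1 library only did not always go with a higher level there: 184 of the 809 GFP-only sites and 9 of the 1263 SETD4-only sites had a higher RPM in the other library. With ratios centred on the median of all sites, 803 of the 809 and 954 of the 1263 were higher in the library that called them. Which class went against its calls more often thus depended on centring. At least 2-fold differences favoured SETD4 at 1651 sites and GFP at 111. After centring on the median of all sites, 273 sites were at least 2-fold higher in SETD4 and 694 in GFP. Centring turned the direction of 1394 sites (28.9%), those with log2 ratios between 0 and 0.77. Subtracting 0.77 cannot turn a site that is at least 2-fold apart, so none of the 1651 or the 111 could turn.

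**Figure D2:**
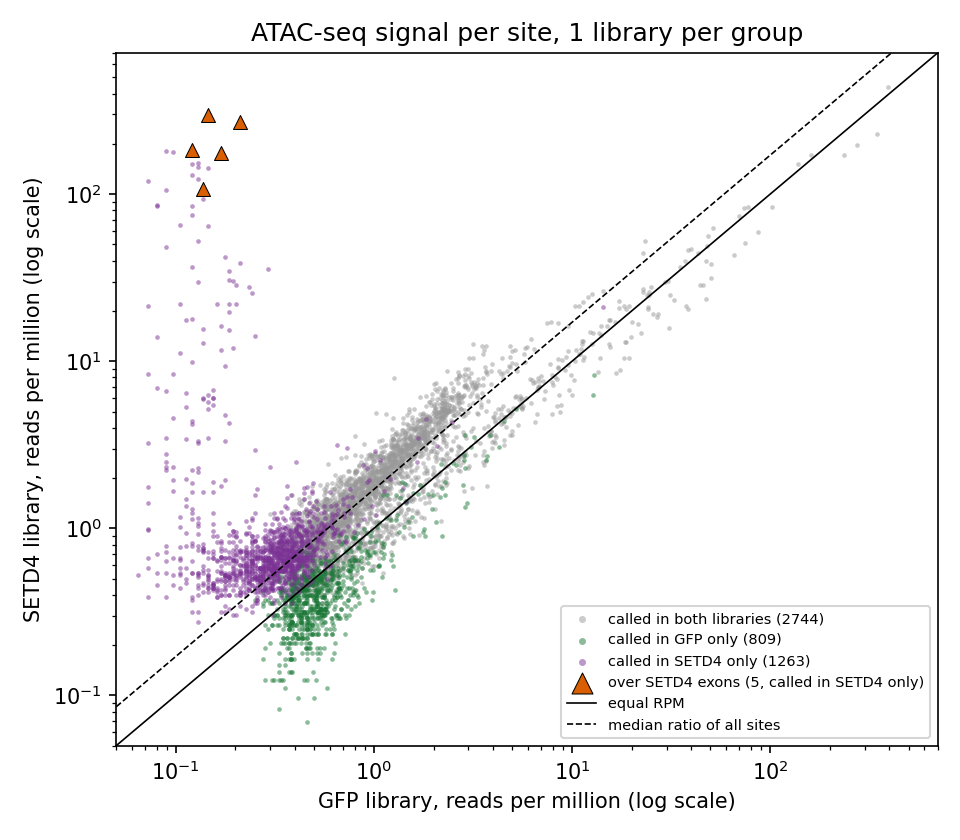
RPM of each site in the GFP library (x axis) and the SETD4 library (y axis), both on log scales; colours give the authors' calls, the solid line equal levels and the dashed line the median ratio of 1.71. The 5 SETD4 sites and other sites called in SETD4 only stand at the upper left, and the sites with most reads in the GFP library lie below the dashed line, some of them below the line of equal levels.

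Before centring, large differences lay on 1 side only. Outside SETD4, 116 sites on 21 chromosomes were more than 8-fold higher in the SETD4 library, 42 of them more than 100-fold, while 0 sites were more than 8-fold higher in the GFP library. Centring would move every log2 ratio by 0.77 toward GFP, so the 0 for GFP need not hold after it. These 116 sites held 214533 reads in the SETD4 library, 20.1% of its reads in the table, against 1765 in the GFP library. By the rule for named genes, the largest differences outside SETD4 were at an intron of PLSCR4, which encodes a phospholipid scramblase family member (chromosome 3, 146214674 to 146214893), and at a site whose closest start was that of SHOX, a homeobox gene of skeletal growth (chromosome X, 686701 to 686920). The PLSCR4 site had 11054 reads against 14 (log2 ratio 10.30, 95% counting interval 9.65 to 11.27), and the SHOX site 11065 against 15 (10.21, 9.58 to 11.14). The site nearest B3GAT1, a glucuronyltransferase gene (chromosome 11, 134394363 to 134394587), had 9465 reads against 14, a log2 ratio of 10.08. An intronic site of JPH1, a junctophilin gene (chromosome 8, 74281185 to 74281402), had 6185 against 9, a log2 ratio of 10.05. The last intron of SPRY4, an inhibitor of receptor tyrosine kinase signalling (chromosome 5, 142315058 to 142315282), had 8892 against 15, a log2 ratio of 9.89. Intron 6 of HTR4, a serotonin receptor gene, the 3′ untranslated region of MYPN, a sarcomere protein gene, the last exon of ZBED4 and the last intron of CLIC5 followed, with log2 ratios of 9.46, 9.27, 9.08 and 8.67. The mean over all HTR4 sites was 3.16, so other sites of that gene lay far lower. Of the 116 sites, 13 lay within 1 kb of a start. One of these, near IQGAP1 (chromosome 15, 90388009 to 90388227) and chosen after its values were seen, had 1019 reads against 30.

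Of the 809 sites called in the GFP library only, 108 were at least 2-fold higher there, against 742 of the 1263 SETD4-only sites in the other direction. Among those above the median of all sites in mean RPM, 8 genes qualified under the naming rule, and the largest difference was at a site closest to DCUN1D4 (chromosome 4, 50720670 to 50721018) and far from its start, with 121 reads against 40 (log2 ratio -0.80, 95% counting interval -1.38 to -0.30). Intron 1 of TTC28 (chromosome 22, 28669161 to 28670071) had 175 reads against 73 (log2 ratio -0.48, interval -0.90 to -0.09). The counting intervals of the other 6, KIF26B, GHR (the growth hormone receptor gene), SSU72L1, the defensin genes DEFB125 and DEFB115, and CTNND2, included 0, with log2 ratios from -0.20 to 0.28. Their upper bounds, from 0.25 to 0.76, all lay below the median of all sites, 0.77. These sites were picked for low ratios. The GHR, SSU72L1, DEFB125 and DEFB115 sites were assigned by closest start only, at distances of -63692, -6489, -25870 and -204822 bp. The DEFB115 site lay in a group of 14 sites at 31051944 to 31187361 on chromosome 20. Larger differences lay at sites below that median level, such as intron 5 of FHOD3 (chromosome 18, 36557127 to 36557348), chosen after its values were seen, with 61 reads against 6 (log2 ratio -2.37, interval -4.07 to -1.37).

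Few sites lay at gene starts. Of all sites, 171 (3.55%, exact 95% interval 3.05% to 4.11%) were within 1 kb of an annotated transcription start site, 1780 (37.0%) were centred in introns, 147 (3.05%) in exons or untranslated regions, and 2889 between genes. Sites called in SETD4 only lay within 1 kb of a start in 56 of 1263 cases (4.43%, 3.37% to 5.72%) and sites called in GFP only in 18 of 809 (2.22%, 1.32% to 3.49%). These intervals overlapped. Introns held 43.2% (40.5% to 46.0%) of the SETD4-only sites and 32.1% (28.9% to 35.5%) of the GFP-only sites, and the reverse held between genes, with 53.2% (50.4% to 56.0%) and 66.4% (63.0% to 69.6%). The median log2 ratio was 0.96 (0.89 to 1.02) at the 171 sites near starts, 0.86 (0.84 to 0.89) in introns and 0.67 (0.63 to 0.70) between genes. Among sites above the median in mean RPM, 8.41% of the SETD4-only and 1.00% of the GFP-only sites lay within 1 kb of a start. Without the sites more than 8-fold apart, left out after the data were seen, the SETD4-only share was 6 of 112 (5.36%, 1.99% to 11.3%) among these and 43 of 1142 (3.77%, 2.74% to 5.04%) at any level.

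By chromosome, sites called in SETD4 only outnumbered those called in GFP only on 20 of the 24 chromosomes with at least 50 sites. The median log2 ratio ran from 0.44 (chromosome 20) to 0.88 (chromosome 22) over the autosomes. It was lower, 0.20, for sites placed on chromosome Y, where 71 of the 103 sites lay in 1 dense cluster. Whether these cells carry a Y chromosome was not examined, so the reads placed there may belong elsewhere. The 3 sites with most reads in the GFP library lay beside centromeres, and there the libraries were closer to each other than at the median site or the GFP library was higher. The highest, on chromosome 3 (93470259 to 93470899), had an RPM of 395.5 in the GFP library and 436.9 in the SETD4 library, a log2 ratio of 0.14. On chromosome 1 (125178795 to 125180773) the RPM was 344.7 in GFP and 228.8 in SETD4, a log2 ratio of -0.59, and on chromosome 16 (46398599 to 46401662) 273.3 against 196.5, a log2 ratio of -0.48. These sites were picked by their read number after the data were seen. Summed over sites, the log2 ratio was -0.06 on chromosome 1 and -0.12 on chromosome 16, while the median site of these chromosomes was at 0.86 and 0.76. Chromosome 21, which holds SETD4, had a summed log2 ratio of 3.40 and a median of 0.59.

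**Figure D3:**
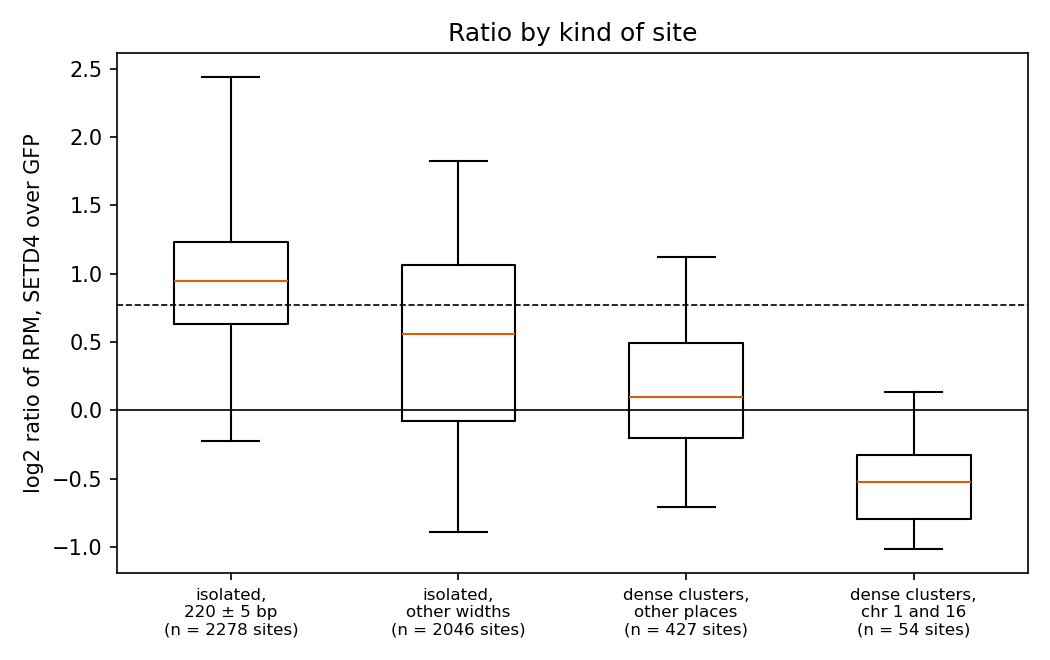
Log2 ratio of RPM, SETD4 over GFP, by kind of site: boxes give the quartiles and median, whiskers the 5th and 95th percentiles over sites; the solid line is 0 and the dashed line the median of all sites, 0.77. Dense clusters are sites with at least 4 others within 50 kb, a grouping chosen after the data were seen that leaves out the 5 SETD4 sites and 6 sites near TTC34, and medians run from 0.94 for isolated sites within 5 bp of a width of 220 bp to -0.53 for clusters on chromosomes 1 and 16.

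The gene lists fixed beforehand had few members in the table: 30 of 404 genes had a site, 10 of them with a site called in SETD4 only and 3 with one called in GFP only. None of the 13 lists with a measured member had a median outside the middle 95% of 10000 random lists of the same size matched on mean level. The values below are therefore descriptions, to be read against the median of all genes with a site, 0.88. For heterochromatin factors, 3 of 28 genes were measured. Besides SETD4, EHMT1 and KDM4C, which encode an H3K9 methyltransferase and an H3K9 demethylase, had sites called in both libraries with log2 ratios of 1.04 and 1.34. Of the 30 cell cycle inhibitors and quiescence genes, 4 were measured (median 0.92, percentile 66.8). TXNIP, a thioredoxin inhibitor, had a SETD4-only site in its 3′ untranslated region with 41 against 35 reads (log2 ratio 1.00, interval 0.32 to 1.70), and GAS6, a growth-arrest ligand, a GFP-only site with 21 against 47 reads (-0.35, -1.20 to 0.38). FOXO1, a forkhead transcription factor, and RBL1, a retinoblastoma-family protein, had sites in both, at 0.90 and 0.95. Of the 35 proliferation genes, CDC25A (0.98) and MKI67 (0.37) were measured, for a list median of 0.67 (percentile 42.0). The MKI67 site was called in GFP only, yet its interval, -0.31 to 1.01, included 0 as well as 0.88.

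Among 25 breast cancer stem cell markers only ITGA6, the integrin alpha-6 gene, had a site, called in both libraries, with 216 against 227 reads (log2 ratio 0.70, percentile 15.3). The Wnt, Notch and Hedgehog list had 3 measured genes, all called in both (median 0.98, percentile 38.9), led by a site near FZD1, a Wnt receptor gene, with 427 against 257 reads (log2 interval 1.28 to 1.74). The luminal list had the lowest median, 0.23 (percentile 4.47), from 2 of 32 genes: PGR, the progesterone receptor gene, at 0.08, and BCL2, an inhibitor of apoptosis, at 0.38. The 2 BCL2 sites differed in direction, at -0.46 and 1.23. BCL2 was also the 1 measured gene of the apoptosis list (percentile 6.05). With only the site of highest signal per gene, the luminal median was 0.65 (percentile 25), no longer the lowest, and the apoptosis value 1.23 (percentile 75.1). Of the basal genes only ANXA1, annexin A1, was measured (1.37, percentile 83.9). The epithelial-mesenchymal list had 3 (median 1.15, percentile 85.9): OVOL2, a repressor of that transition, had a SETD4-only site with 48 against 20 reads (2.00, 1.26 to 2.87), CDH2, N-cadherin, averaged 1.15 over 4 sites, and SMAD2 was at 0.48.

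Of the 41 EGF, FGF, PI3K and MAPK genes 5 were measured, 4 of them with a SETD4-only site, at a list median of 1.25 (percentile 89.2). SPRY4 is given above. JUN, an immediate-early transcription factor, had 91 against 58 reads in its last exon (1.41, 0.93 to 1.92). AKT3, a kinase, had a SETD4-only site at 2.19 (1.41 to 3.13) and a second site, called in both, at 0.31 (-0.23 to 0.82). SPRED2 was at 0.99 and IRS1 at -0.13. The stress and hypoxia list (PDK1 0.64, KLF6 0.68; percentile 31.8) and the genes of MCF7-amplified regions (BRIP1 1.06, CSE1L -0.23; percentile 37.9) had 2 measured genes each. None of the 20 constitutive promoters had a site. Markers of other cell types were limited to LUM, a fibroblast proteoglycan gene, at 1.17, and VWF, an endothelial gene, at 1.31 (percentile 84.6).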

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

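No paired analysis was possible because each group has 1 library and the labels give no replicate numbers; for the same reason no library could be left out. The planned stricter p-value could not be tried, since the table holds no p-values. In place of the authors' calls (1263 SETD4-only and 809 GFP-only sites), a 4-fold threshold gave 214 and 5, sites above the median in mean RPM 214 and 100, and sites over 300 bp wide (chosen after seeing the data) 106 and 127, which turns their order; merging sites kept both counts within 1.5 times. The counts of sites at least 2-fold apart (1651 higher in SETD4, 111 in GFP) became 214 and 5 at 4-fold, 2869 and 325 at 1.5-fold, 1007 and 11 above the median in RPM, 168 and 18 for sites over 300 bp wide and, after centring, 273 and 694; dropping the added count, merging, or leaving out the SETD4 sites moved neither by over 1.5 times. The overall median of 0.77 was 0.90 above the median in RPM, 0.82 without dense clusters and 0.14 for sites over 300 bp wide, the last 2 chosen after seeing the data. Near start sites, SETD4-only and GFP-only shares were 11.1% and 6.80% in a 3 kb window, 0.554% and 0% within 100 bp, 8.41% and 0% at 4-fold (5 sites for GFP), and 8.41% and 1.00% above the median in RPM; in each the SETD4 share was the higher, as it was without sites over 8-fold apart (3.77% and 2.22%, chosen after seeing the data). With only sites within 10 kb of a start, 2 lists in place of 0 left the middle 95%: heterochromatin factors (10.40, percentile 99.1), where SETD4 was the 1 gene left, and the EGF to MAPK list (5.65, percentile 98.0), with 2 genes left. The SETD4 reads cannot be separated from those of the vector. The 2 genes were SPRY4 (9.89) and JUN (1.41), so that value rests on SPRY4, whose site is among those more than 8-fold apart. Without the filter on level, 10 of the 18 genes named by size were named again. For the other changes the cause was not tested beyond the smaller number of sites each setting leaves. Taking each gene's site with most signal turned KIF26B from 0.33 to -0.20 and TTC28 from 0.56 to -0.48; other gene values kept their sign. Low counts per site limit single sites more than the totals.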

Other observations

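All tests in this part but that of gene overlap were chosen after their result had been seen, and each compares sites within 1 pair of libraries. Widths divided the table. Narrow sites, within 5 bp of a width of 220 bp, numbered 2293 (47.6%) and had a median log2 ratio of 0.94, against 0.14 for the 785 sites over 300 bp wide, a difference of 0.80 (bootstrap 95% interval 0.74 to 0.86). Of the 1810 narrow sites called in both libraries with 1 summit per library, 72.7% (70.6% to 74.7%) had summits within 5 bp of each other, against 77 of 366 wide sites. Because sites were merged across the libraries, width itself limits how far apart 2 summits can lie. No conclusion is drawn from this contrast. On the 2 scaffolds that carry ribosomal RNA genes, 28 sites had a median log2 ratio of 0.44, higher in the SETD4 library but below the median of all sites. Scaffold GL000225.1 held 38 clustered sites with a pooled log2 ratio of 0.98, and a group of 6 sites at 2652126 to 2688296 on chromosome 1, where TTC34 lies, one of 2.38 (95% counting interval 2.23 to 2.54).

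The 5 SETD4 sites were called in the SETD4 library only. All 5 were centred on exons or the untranslated region (exact interval of the share 47.8% to 100%). Of the other 1936 sites that overlap a gene, 7.33% were. The 5 sites lie in the same gene, so they are not the independent draws that the interval assumes. Where opening of the endogenous SETD4 gene would place sites was not tested. The contrast therefore cannot decide on such opening, which stays open. DNA of the SETD4 vector, which has no introns, is a candidate source. One of the 5 sites is annotated as 3′ untranslated region, while the labels describe an open reading frame, so how far that site matches the vector stays open. Whether vector DNA would be integrated or carried over as plasmid was not tested.

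Outside SETD4 and before centring, 116 sites were more than 8-fold higher in the SETD4 library and none in the GFP library. Of them, 11.2% (6.10% to 18.4%) lay within 1 kb of a start site, below the 50% set for open promoters as the main source. Few sites of any kind lay there, 3.37% (2.87% to 3.92%) of all others, so that bar decides little. The 116 sites lay near starts more often than other sites did. Reads stacked at single positions may explain them: 93.1% (86.9% to 97.0%) were within 5 bp of a width of 220 bp, against 22.9% (20.4% to 25.4%) of the other SETD4-only sites, 46.5% of all other sites and 1810 of the 2744 sites called in both libraries. Vector integration in gene bodies stays open too. Of the 116 sites, 56.0% (46.5% to 65.2%) overlapped a gene against 39.9% of all other sites, but the interval overlaps that of the other SETD4-only sites (46.1%, 43.2% to 49.1%). Gene overlap cannot decide this, as the share for random positions in the genome was not computed. A change in chromatin caused by SETD4 was not tested, as the design has 1 library per group.

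Dense clusters of sites on chromosomes 1 and 16, grouped after their values were seen, had a median log2 ratio of -0.53 (-0.64 to -0.44) over 54 sites. With the 6 sites near TTC34, which were left out after their high ratio was seen, it was -0.49 (-0.60 to -0.39) over 60. The 427 sites of other clusters had a median of 0.10 (0.06 to 0.15). Values differed within the group. The cluster of 27 sites on chromosome 1 had a median of -0.80 and a summed log2 ratio of -0.74. Both clusters of chromosome 16 were less low, with medians of -0.28 and -0.46 and summed log2 ratios of -0.39 and -0.45. Among the other clusters, 1 at 47068633 to 47308512 on chromosome 5 had a summed log2 ratio of -0.48, below both of chromosome 16. Another, at 90502832 to 90717892 on chromosome 3, had a median of -0.54 but a summed log2 ratio of 0.03 (-0.08 to 0.14). One scaling factor between the libraries cannot give the low values on chromosomes 1 and 16. The median of the clusters there minus that of isolated sites was -1.35 (-1.46 to -1.26), or -1.31 (-1.42 to -1.20) with the 6 sites near TTC34. Medians argue against whole-chromosome copy number as well, since isolated sites on chromosomes 1 and 16 were 0.10 (0.04 to 0.16) higher than those elsewhere. Summed over these isolated sites, the log2 ratio went the other way, at 0.55 against 1.25 elsewhere, so the answer depends on the measure. Reads shared between repeat copies and a difference between the libraries in preparation were not tested and stay open, and the repeat content of these regions was not analysed here. A chromatin difference tied to added SETD4 and the H4K20me3 label stays open as well and is untested with 1 library per group.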
